A study of Rattus norvegicus with 6 samples.

How the data were processed

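Gene expression was measured in whole kidneys of male rats of 2 strains, the Dahl salt-sensitive strain (Dahl S), which develops hypertension on a high-salt diet, and the Lewis strain. Per the design text in the labels, all 6 rats received food with 8% NaCl from an age of 5 weeks, for 8 weeks. Kidney RNA was extracted with TRIzol, labelled with biotin and hybridized to 1 array per rat, with 3 rats per strain. The labels number each rat within its strain, and groups and replicate numbers were taken from the sample titles. Rats on a low-salt diet were not analysed here, so each difference is between salt-fed strains and holds both inherited differences and differences in the response to salt.

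The deposited table holds 1 linear signal intensity for each of 31099 probe sets on each array. Per the labels, the authors computed these intensities with GeneChip Operating Software version 1.4. The scaling target and the detection calls are not given in the sources used here. The intensities had not been brought to a common level: the 2% trimmed mean of an array lay between 119 and 250. The design written before the data were examined had assumed values already scaled per array, and named quantile normalization as an alternative. Because the values were unscaled, quantile normalization of log2(signal + 16) was made the main setting, and the fit of the deposited intensities without normalization was kept as an alternative. The pseudocount of 16 is the lower quartile of all values, a rule fixed beforehand. Fold changes are on this log2(signal + 16) scale, which understates the change of dim genes. Quantile normalization gives every array the same distribution of values, so a shift shared by most genes cannot be seen, and changes are relative to the typical probe set.

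Gene names came from the platform annotation given with the table, updated through gene identifiers to a RefSeq gene table of the GRCr8 assembly. Of 21268 annotated probe sets, 20764 matched that table. Leaving out 57 control probe sets, 20826 probe sets had 1 gene symbol, 436 had several and 9780 had none in this annotation. No gene was named from a probe set with several symbols. The RefSeq table served for gene names, and its gene positions were used to find overlaps and neighbours of genes.

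A probe set was tested if its normalized value exceeded the median of all values on at least 3 of the 6 arrays, whichever these were, which left 15797 probe sets. Among these, 12656 had 1 symbol, 311 had several and 2830 had none. Dahl S was compared with Lewis by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. All adjusted p-values are from limma unless another test is named. Standard errors (SE) are those of limma's moderated fit, except for array controls, where they are taken over the arrays' medians, and each strain had n = 3 arrays. The number of arrays limits the precision: an exact two-sided permutation test of 3 against 3 cannot give a p below 0.1. The table states no measure of signal over background, so the filter on low values stands in for it.

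For tests by gene, the probe set with the highest mean over all 6 arrays stood for the gene, which gave 9540 genes, 2392 of them with more than 1 tested probe set. Sets of genes were 28 lists of renal, immune and other-tissue genes fixed before the data were examined. Lists with at least 5 measured members, 25 in number, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. The fry test, which asks whether the members of a list move on balance 1 way, was run beside them. Members of the lists were counted past the threshold adjusted over all probe sets tested and adjusted over the list alone.

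The genes named in the text follow a rule written beforehand. The rule takes the 10 genes with the largest difference in each direction, among genes past the threshold whose strain ranges did not overlap, without symbols that start with LOC or RGD. It adds up to 4 members of each list with the smallest adjusted p past the threshold, and a short set of kidney genes given as values whatever they were. Some of that set had no tested probe set carrying the symbol alone and are not reported here. The rule covers 115 measured genes, of which 109 passed the threshold. A gene named outside the rule is said to have been chosen after its values were seen.

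Before use, the steps were tested on simulated data with the means and spreads of the real arrays. In these data 200 probe sets were changed by known amounts between 3 and 3 arrays, and 15662 probe sets were tested. The fit recovered 44.8% of simulated changes of 0.5 log2, 88.1% of changes of 1 and 98.5% of changes of 2. It made 161 calls, of which 7 (4.35%) fell on unchanged probe sets. A shifted gene list, that of the proximal tubule, was found, and 0 lists without a simulated shift were called. All its members were moved by the same amount, larger than the median found for that list in the real data. Smaller or uneven shifts of a list were not tried. The simulated noise was drawn independently for each probe set. The simulation therefore cannot show how often lists are called falsely where genes vary together.

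Alternatives fixed before the data were examined were the deposited values, scaling to a common median, no pseudocount and 1 of 64, no filter and a stricter filter, other variance priors, a replicate block, stricter thresholds, leaving out each array, and other ways of testing lists. The design had set the filter on the values of the table as deposited. Applying it to normalized values was a choice made after seeing the data, along with the switch in normalization. The filter on the deposited values, with normalized values in the fit, was kept as an alternative. Alternatives chosen after seeing the data were member counts of lists without Lewis array 1 and probe sets with a single gene symbol alone. Figures were drawn with Python 3.11.15.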

Results

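The study asked which genes are expressed differently in the kidneys of Dahl S and Lewis rats, both fed a high-salt diet. Whole-kidney RNA of 3 Dahl S and 3 Lewis rats was measured, each rat on its own array of 31099 probe sets. Before normalization the 2% trimmed mean signal was 119, 230 and 175 on Lewis arrays 1, 2 and 3, and 225, 250 and 205 on Dahl S arrays 1, 2 and 3. The strain means were 227 ± 22.6 for Dahl S and 174 ± 55.6 for Lewis (SD, n = 3 each, exact permutation p = 0.3, two-sided). The poly-A spike controls, bacterial transcripts that can be added to RNA before labelling, were 0.91 higher in Dahl S on the log2 scale (median of 24 probe sets, SE 0.26 over the arrays). The controls added at hybridization differed by -0.04 (median of 18 probe sets, SE 0.16 over the arrays).

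**Figure D1:**
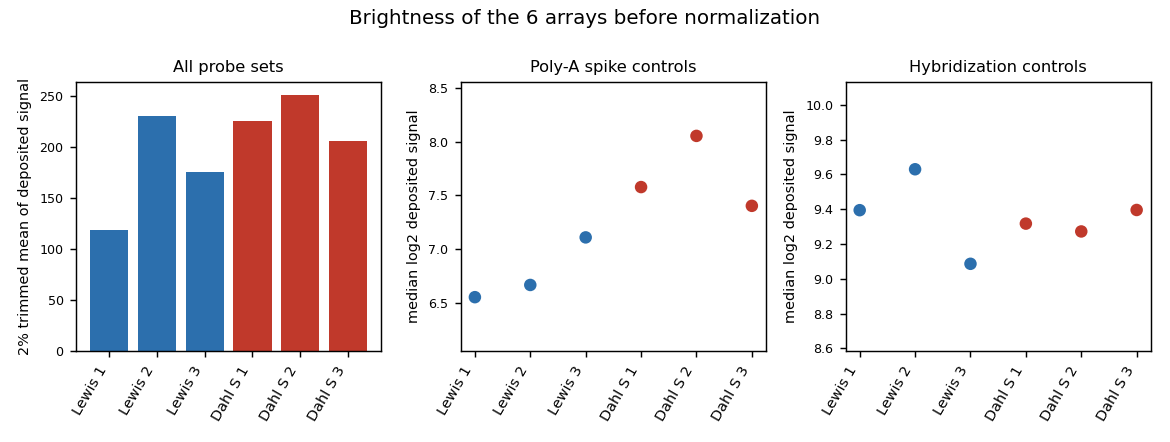
Brightness of the 6 arrays before normalization. Bars give the 2% trimmed mean of the deposited signal over all probe sets of an array, and points the median log2 signal of the poly-A spike controls and of the hybridization controls, with Lewis in blue and Dahl S in red. Lewis array 1 was the dimmest at 119 and Dahl S array 2 the brightest at 250, and the spike controls of all Dahl S arrays lay above those of all Lewis arrays.

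After normalization the arrays of a strain resembled each other more than those of the other strain. Correlations over the probe sets tested were 0.991 to 0.993 within Dahl S, 0.980 to 0.988 within Lewis and 0.958 to 0.970 between strains; these are across probe sets, which are not independent replicates. The component that separated the strains held 62.8% of the variance. No array duplicated another.

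Kidneys of salt-fed Dahl S rats carried more RNA of tubular injury markers, extracellular matrix genes, chemokines and cytokines, and interferon-stimulated genes than kidneys of salt-fed Lewis rats, and less RNA of proximal tubule, cytochrome P450 and fatty acid oxidation genes, each relative to the typical probe set. The injury marker Havcr1, which encodes kidney injury molecule 1, was 8.39-fold higher in Dahl S (log2 difference 3.07, SE 0.16, adjusted p = 8.4e-08; 3.41 with no pseudocount and 2.43 with one of 64). Acsm3, a medium-chain acyl-CoA synthetase gene, was 10.5-fold higher (3.39, SE 0.13, adjusted p = 7.4e-09). The male-biased cytochrome P450 gene Cyp2c11 was 7.80-fold lower (-2.96, SE 0.08, adjusted p = 4.8e-10).

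In all, 1343 of 15797 probe sets were higher in Dahl S and 1224 were lower, 16.2% of those tested. By gene, 862 of 9540 were higher and 727 lower. A difference of at least 2-fold was reached by 134 of the higher and 110 of the lower probe sets. Strain ranges did not overlap in 5440 probe sets (34.4%), where chance gives 10%. In the deposited values without normalization the tested probe sets were 0.41 higher in Dahl S at the median on the log2 scale, and 666 were called higher and 47 lower, so that 93.4% of calls were higher against 52.3% after normalization. Calls fell to 806 higher and 772 lower without Dahl S array 1, to 834 and 804 without Dahl S array 2, and to 764 and 727 without Dahl S array 3.

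Among the genes with the largest differences, several have known parts in the kidney or the immune system. Tinag, which encodes a basement membrane protein of renal tubules, was 9.45-fold higher in Dahl S (3.24, SE 0.11, adjusted p = 2.2e-09). Slpi, a secreted protease inhibitor gene, was 5.12-fold higher (2.36, SE 0.12), and Itgal, the integrin alpha L chain of leukocytes, was higher by 2.13 (SE 0.20). Fos, an immediate-early transcription factor gene, was higher by 2.66 (SE 0.14). Olfml1 (2.66), Tmem35b (3.02), Eri2 (2.82) and the class I MHC gene RT1-CE16 (2.27) completed the 10 genes that rose most. The Lewis signals of Fos, Itgal and Tmem35b lay near the pseudocount, so the size of their differences depends on it: with no pseudocount and with one of 64 they were 3.42 and 1.72 for Fos, 2.93 and 1.28 for Itgal, and 4.60 and 1.87 for Tmem35b. In the GRCr8 assembly Eri2 overlaps Acsm3, so that the signals of these neighbours are not independent evidence, and a second probe set of Eri2 differed by 0.74 (adjusted p = 0.026). A second probe set of Olfml1 gave 2.33 (adjusted p = 7.4e-09).

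Among the genes that fell most, after Cyp2c11, were Dusp15 (-2.66, SE 0.16), a phosphatase gene, and Gtpbp4 (-2.54, SE 0.06), a nucleolar GTP-binding protein gene whose other probe set gave -3.26 (adjusted p = 7.5e-11). The retinol dehydrogenase gene Rdh16 was 4.33-fold lower in Dahl S (-2.12, SE 0.11). The coagulation genes F5 (-1.99, SE 0.10) and Serpinc1, which encodes antithrombin (-1.97, SE 0.10), were each about 4-fold lower. Setd1b (-2.18), Snap91 (-1.99), Mis18a (-1.97) and RT1-CE5 (-2.11) completed this group. Dusp15, Snap91 and Mis18a were dim in Dahl S, and with no pseudocount and with one of 64 gave -3.90 and -1.54, -2.70 and -1.19, and -2.49 and -1.26. Setd1b was dim in Dahl S as well (deposited signals 32.1, 68.4 and 38.1 on arrays 1, 2 and 3). The size of its difference therefore also depends on the pseudocount. The other probe sets of RT1-CE5 gave -4.30, -1.89 and -3.53. Class I MHC genes differ in sequence between rat strains, and RT1 probe sets can share sequence, so the values of RT1-CE16, RT1-CE5 and other RT1 genes are uncertain as measures of RNA level.

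Of 28 fixed gene lists, 25 had enough measured members to be tested, and 18 passed camera's threshold, 9 towards higher and 9 towards lower values in Dahl S. With an estimated correlation between genes 8 of these passed, 5 up and 3 down. The fry test called 22 lists. They included the reference (housekeeping) list (fry adjusted p = 0.0061) and the complement, renin-angiotensin-aldosterone and smooth muscle lists, none of which camera called in the main setting. A call by fry thus did not set a list apart from the reference genes.

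**Figure D2:**
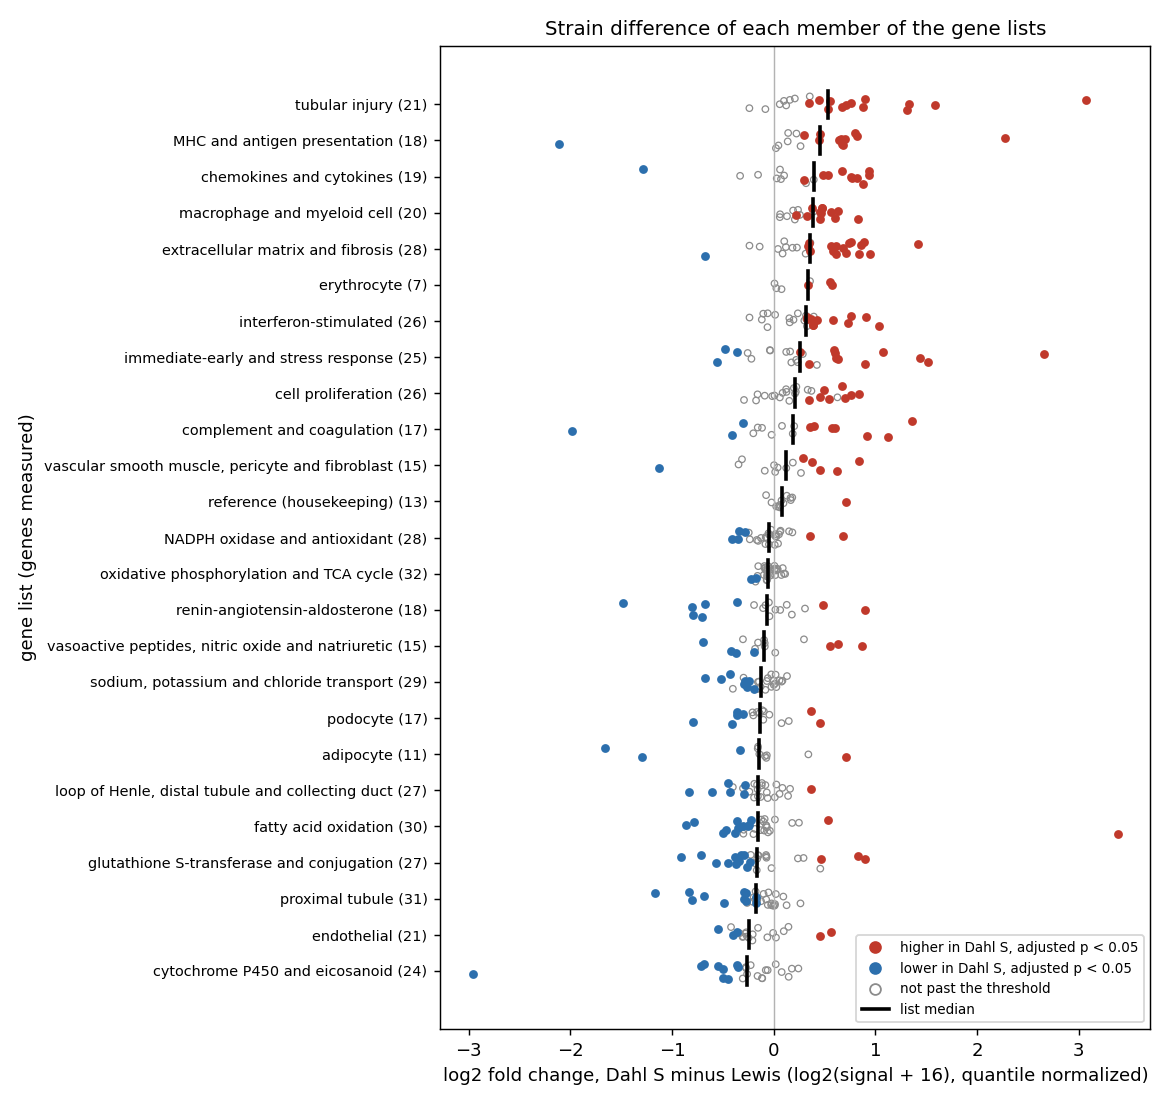
Strain difference of every measured member of the 25 tested gene lists. The x axis is the log2 fold change of Dahl S minus Lewis after quantile normalization of log2(signal + 16), each point is 1 gene, filled red or blue where adjusted p was under 0.05 and open otherwise, and black bars are list medians. Medians run from 0.53 for tubular injury to -0.27 for cytochrome P450 and eicosanoid genes.

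Markers of tubular injury rose in Dahl S. Of 21 measured members 13 were higher, 0 lower and 8 did not pass (15 higher and 1 lower adjusted over the list alone), with a median of 0.53 (adjusted p = 2.6e-11; adjusted p = 0.034 with an estimated correlation). Beside Havcr1, the chaperone gene Clu, clusterin, was 3.01-fold higher (1.59, SE 0.07, adjusted p = 1.8e-08). The iron-binding lipocalin gene Lcn2, known as NGAL, rose by 1.33 (SE 0.11), and Spp1, osteopontin, by 0.88 (SE 0.07). The count stayed at 13 or 14 with any single array left out, and was 12 with scaling to a common median and 9 in the deposited values.

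Extracellular matrix genes rose as well. Of 28 measured members 16 were higher, 1 lower and 11 did not pass (19 higher and 2 lower adjusted over the list alone), with a median of 0.36 (adjusted p = 6.2e-09; adjusted p = 0.034 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, was 2.68-fold higher (1.42, SE 0.10, adjusted p = 1.6e-06). The proteoglycan gene Dcn, decorin, rose by 0.86 (SE 0.06), and the fibrillar collagen genes Col3a1 and Col5a2 by 0.74 (SE 0.07) and 0.71 (SE 0.09). The single member that fell was Sparc (-0.68, SE 0.10), a matrix protein gene, which was named after its value was seen and whose call was lost without Lewis array 1 or 2. The number higher was 12 without Lewis array 2 or any 1 Dahl S array. Deposited values gave 10 members higher and 0 lower, and scaling to a common median gave 17 higher and 2 lower.

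Genes of macrophages and of immune signalling were higher in Dahl S. Of 20 macrophage and myeloid genes 12 rose, 0 fell and 8 did not pass (13 higher adjusted over the list alone), with a median of 0.38 (adjusted p = 4.5e-07; adjusted p = 0.053 with an estimated correlation). Aif1, a marker of activated macrophages, rose by 0.83 (SE 0.10), Cd68, a lysosomal membrane protein gene, by 0.61 (SE 0.11), Lcp1 by 0.56 (SE 0.10) and the protease gene Ctss by 0.47 (SE 0.08). Without Dahl S array 1, 6 of these genes passed, and 4 did in the deposited values. Of 3 measured lymphocyte genes the pan-leukocyte gene Ptprc rose by 0.97 (SE 0.11) and the T cell kinase gene Lck by 0.54 (SE 0.14). The third, Cd4, named after its value was seen, differed by 0.10 (SE 0.13). The call of Lck was lost without Dahl S array 2 (0.49, adjusted p = 0.088) and without Dahl S array 3 (0.53, adjusted p = 0.077).

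Chemokine and cytokine genes moved mostly up: of 19 measured, 10 rose, 1 fell and 8 did not pass (12 higher and 2 lower adjusted over the list alone), with a median of 0.39 (adjusted p = 4.5e-05; adjusted p = 0.034 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.062). The monocyte chemoattractant gene Ccl2 rose by 0.82 (SE 0.10) and Cxcl16 by 0.77 (SE 0.09). The exception was Cxcl13, a chemokine that attracts B cells, which was 2.44-fold lower in Dahl S (-1.29, SE 0.11, adjusted p = 6.4e-06), and 2 members fell without Lewis array 3 and 0 in the deposited values. Of 26 interferon-stimulated genes 11 rose, 0 fell and 15 did not pass (13 higher adjusted over the list alone), with a median of 0.32 (adjusted p = 1.1e-05; adjusted p = 0.034 with an estimated correlation). Ifi27 rose by 1.04 (SE 0.08), the transcription factor gene Irf1 by 0.91 (SE 0.10), the guanylate-binding protein gene Gbp2 by 0.76 (SE 0.10) and Parp9 by 0.59 (SE 0.10). The interferon count fell to 7 without Lewis array 3, to 6 without Dahl S array 1 or 2 and to 5 without Dahl S array 3, and was 5 in the deposited values.

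MHC and antigen presentation genes rose on balance, with 11 of 18 members higher, 1 lower and 6 not past the threshold (the same counts adjusted over the list alone), and a median of 0.45 (adjusted p = 4.8e-07; adjusted p = 0.053 with an estimated correlation). The class II genes RT1-Da and RT1-Db1 gave 0.82 (SE 0.07) and 0.64 (SE 0.07). Strain differences in probe sequence were not masked, which leaves these values, and the call of a list with many RT1 members, uncertain as differences in RNA level. Complement and coagulation genes went both ways, with 7 of 17 higher, 3 lower and 7 not past the threshold (8 higher and 3 lower adjusted over the list alone), and the list did not pass (adjusted p = 0.082; adjusted p = 0.148 with an estimated correlation), though it did without a filter (0.0068), without Dahl S array 2 (0.048) and over members of no other list (0.040). The central complement gene C3 rose by 1.12 (SE 0.12), the protease gene C1s by 0.60 (SE 0.07) and the fibrinogen chain gene Fga by 1.36 (SE 0.11), against the fall of F5. The other members that fell, named after their values were seen, were Thbd (-0.41) and Plat (-0.30), which encode thrombomodulin and tissue plasminogen activator. In this list 1 member was lower, and 5 higher, without Lewis array 2 or any 1 of the 3 Dahl S arrays. The deposited values gave 3 higher and 1 lower.

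**Figure D3:**
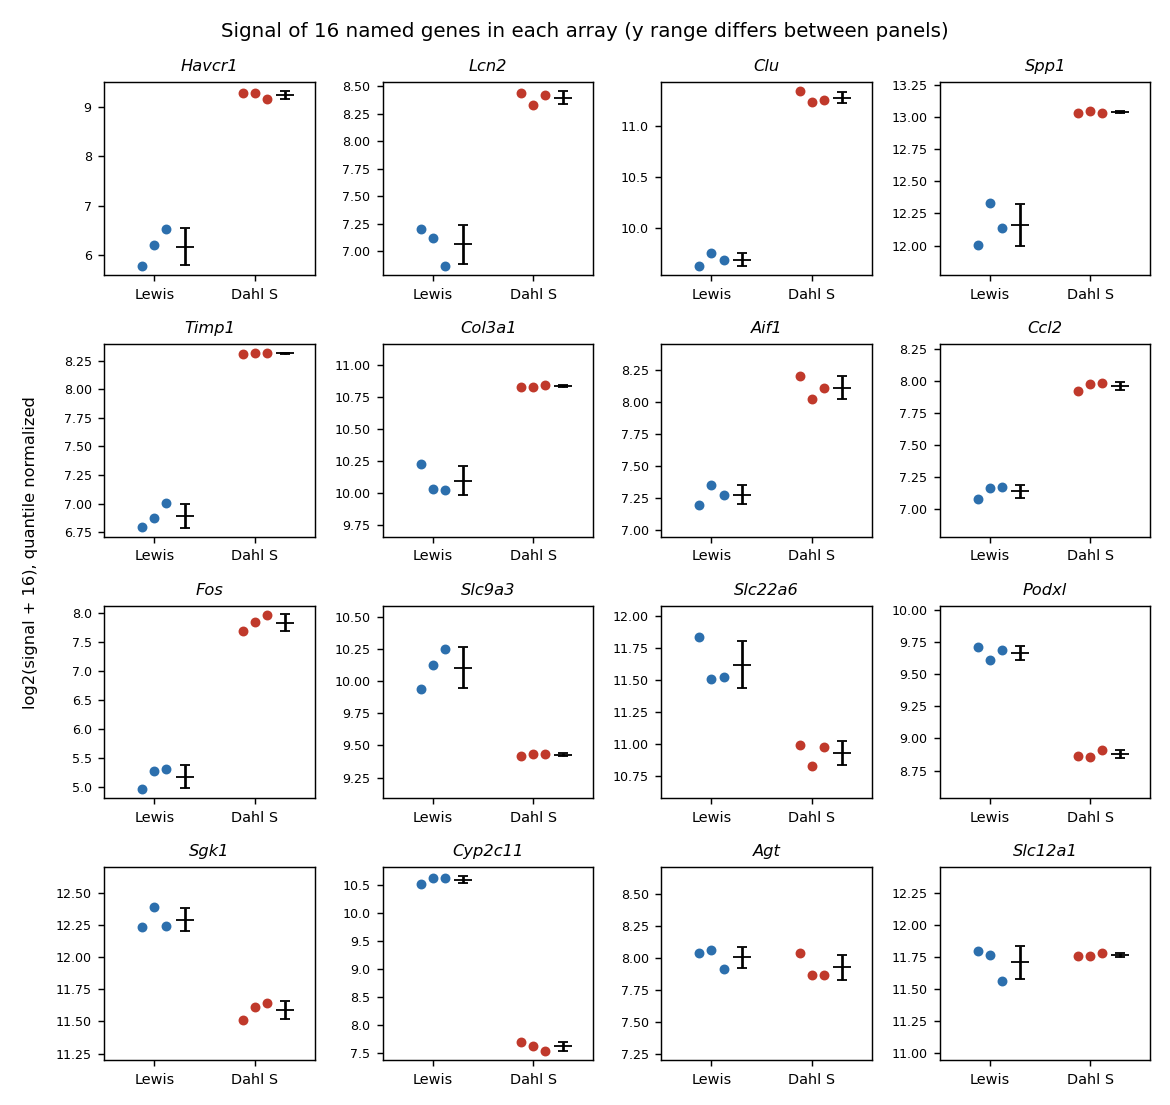
Normalized log2(signal + 16) of 16 named genes on each array, Lewis in blue and Dahl S in red, with the mean and SD of each strain (n = 3) beside the points; the y range differs between panels. Strain ranges do not overlap for 14 of the genes, while those of Agt and Slc12a1, which did not pass the threshold, do.

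Immediate-early and stress genes were higher in Dahl S on balance. Of 25 measured, 11 rose, 3 fell and 11 did not pass (14 higher and 4 lower adjusted over the list alone), with a median of 0.26 (adjusted p = 6.0e-05; adjusted p = 0.034 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.062). After Fos, the largest rises were those of the transcription factor genes Atf3 (1.52, SE 0.17; 1.89 with no pseudocount and 0.99 with one of 64), Egr1 (1.44, SE 0.10) and Klf6 (0.90, SE 0.11). The members that fell, named after their values were seen, were Klf2 (-0.56), Zfp36 (-0.48) and Gadd45a (-0.36), and 0 members fell without Dahl S array 1 or in the deposited values. Of 26 proliferation genes 8 rose, 0 fell and 18 did not pass (10 higher and 1 lower adjusted over the list alone), with a median of 0.21 (adjusted p = 9.6e-04; adjusted p = 0.123 with an estimated correlation; adjusted p = 0.328 with the stricter filter). The replication licensing genes Mcm6 (0.84, SE 0.17) and Mcm4 (0.67, SE 0.13) rose, as did the proliferation marker Mki67 (0.76, SE 0.13) and the ribonucleotide reductase gene Rrm1 (0.49, SE 0.10). In this list 5 members were higher without Dahl S array 1, and 1 was lower without Lewis array 1.

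Markers of blood moved with the genes that rose. Of 7 erythrocyte genes 3 were higher and 4 did not pass (4 higher adjusted over the list alone), with a median of 0.34 (adjusted p = 0.028; adjusted p = 0.123 with an estimated correlation). The call was also lost in the deposited values, without a filter, with the stricter filter and as the mean of a gene's probe sets (adjusted p 0.050 to 0.15). The globin genes Hba-a3 and Hbb rose by 0.57 (SE 0.13) and 0.34 (SE 0.09) and the haem synthesis gene Alas2 by 0.56 (SE 0.14). None of the 3 passed without Dahl S array 2, where they gave 0.46, 0.34 and 0.45 (adjusted p = 0.064, 0.069 and 0.077), and Hbb was also lost without Dahl S array 3 (0.31, adjusted p = 0.086) and with scaling to a common median (0.17, adjusted p = 0.26). In the deposited values 1 member was higher.

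The list of sodium, potassium and chloride transport genes was lower in Dahl S. Of 29 measured, 0 rose, 8 fell and 21 did not pass (also 8 lower adjusted over the list alone), with a median of -0.13 (adjusted p = 0.0030; adjusted p = 0.128 with an estimated correlation). The sodium-hydrogen exchanger gene Slc9a3 fell by 0.68 on the log2 scale (SE 0.09, adjusted p = 1.9e-04), the sodium pump regulator Fxyd4 by 0.43 (SE 0.08) and the bicarbonate cotransporter gene Slc4a4 by 0.29 (SE 0.06), whose other probe set gave -0.14 (adjusted p = 0.34). The loop diuretic-sensitive cotransporter gene Slc12a1 differed by 0.06 (SE 0.07, adjusted p = 0.61) and the thiazide-sensitive cotransporter gene Slc12a3 by -0.40 (SE 0.22, adjusted p = 0.26). The Slc12a3 difference was -0.04 without Lewis array 1 and ran from -0.62 to -0.37 without any 1 of the others. Scnn1a, the alpha subunit of the epithelial sodium channel, differed by -0.52 (SE 0.16, adjusted p = 0.042), a call lost without any 1 of Lewis arrays 1 and 2 and Dahl S arrays 1, 2 and 3, where the difference ran from -0.60 to -0.31; its other probe set gave -0.47 (adjusted p = 0.17). The number of members that fell was 3 without Lewis array 2 or without Dahl S array 1 or 2, 4 without Dahl S array 3, and 0 in the deposited values. Without Lewis array 1, 1 member rose and 6 fell. Of the 29 members 11 belong to other lists as well, and over members of no other list the list's adjusted p was 0.011.

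The renin-angiotensin-aldosterone list held changes in both directions: of 18 measured, 2 rose, 6 fell and 10 did not pass (2 higher and 7 lower adjusted over the list alone), and the list did not pass (median -0.06, adjusted p = 0.061; adjusted p = 0.128 with an estimated correlation). It passed with scaling to a common median (adjusted p = 0.018), as the mean of a gene's probe sets (0.049), without Lewis array 2 (0.040) and without Dahl S array 3 (0.033). The kinase gene Sgk1 fell by 0.70 on the log2 scale (SE 0.06, adjusted p = 1.1e-05), Fkbp5 by 0.79 (SE 0.11) and Tsc22d3 by 0.68 (SE 0.07). Per1 (-0.81, SE 0.13) and the angiotensin-processing peptidase gene Prcp (-1.48, SE 0.20), both named after their values were seen, also fell. Mme, which encodes the peptidase neprilysin, rose by 0.90 (SE 0.07), and Anpep, an aminopeptidase gene named after its value was seen, by 0.49 (SE 0.07). Enpep, which encodes aminopeptidase A, gave -0.36 (SE 0.06) on its brighter probe set and 0.50 (adjusted p = 0.12) on the other, and 0.07 as the mean of both. Agt, angiotensinogen, differed by -0.08 (SE 0.10, adjusted p = 0.63), the mineralocorticoid receptor gene Nr3c2 by -0.10 (SE 0.11, adjusted p = 0.57) and Hsd11b2, which inactivates glucocorticoids, by -0.19 (SE 0.07, adjusted p = 0.070; -0.30 and adjusted p = 0.018 with scaling to a common median). In the deposited values 0 members fell and 1 rose.

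Vasoactive genes also went both ways, with 3 of 15 higher, 4 lower and 8 not past the threshold (3 higher and 5 lower adjusted over the list alone; list adjusted p = 0.214, and 0.028 with the stricter filter). The soluble guanylate cyclase gene Gucy1b1 rose by 0.87 (SE 0.12) with 1.23 on its other probe set. Gucy1a1, the other subunit of the enzyme, gave 0.64 (SE 0.09) and -0.30 (adjusted p = 0.11) on its probe sets and did not pass as their mean (0.17, adjusted p = 0.23). The arginase gene Arg2 fell by 0.70 (SE 0.08) on the log2 scale and the kallikrein gene Klk1 by 0.42 (SE 0.06). Of members named after their values were seen, Adm, adrenomedullin, rose by 0.55, and Ddc and Ddah1 fell by 0.37 and 0.20. In the deposited values 0 members fell.

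Proximal tubule genes were lower in Dahl S. Of 31 measured, 0 rose, 11 fell and 20 did not pass (13 lower adjusted over the list alone), with a median of -0.17 (adjusted p = 1.1e-05; adjusted p = 0.034 with an estimated correlation). The lactate transporter gene Slc5a12 fell by 0.84 on the log2 scale (SE 0.08, adjusted p = 2.0e-05), the organic anion transporter gene Slc22a6 by 0.69 (SE 0.09) and the gluconeogenic gene Pck1 by 0.49 (SE 0.05). Cyp27b1, which activates vitamin D, fell by 1.17 (SE 0.18; -1.61 with no pseudocount and -0.66 with one of 64). The number that fell was 7 without Dahl S array 2, 6 without Dahl S array 3, 19 with scaling to a common median and 0 in the deposited values. The 3'/5' signal ratios of the control genes, a sign of RNA integrity, were 2.25 ± 0.070 in Dahl S and 2.33 ± 0.297 in Lewis for actin (SD, n = 3 each, exact permutation p = 0.8), 1.10 ± 0.012 and 1.13 ± 0.056 for GAPDH (exact permutation p = 0.8), and for hexokinase 1.93 ± 0.079 and 1.77 ± 0.156 (exact permutation p = 0.2).

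The loop of Henle, distal tubule and collecting duct list was lower as well, with 1 of 27 members higher, 6 lower and 20 not past the threshold (1 higher and 10 lower adjusted over the list alone), and a median of -0.16 (adjusted p = 9.6e-04; adjusted p = 0.103 with an estimated correlation). Of these 27 members 14 belong to other lists as well, so this is not wholly separate evidence. Over members of no other list the list's adjusted p was 0.011. The water channel gene Aqp4 fell by 0.83 (SE 0.08) on the log2 scale, the urea transporter gene Slc14a2 by 0.45 (SE 0.08) and the calcium-binding protein gene S100g by 0.61 (SE 0.13). The member that rose, named after its value was seen, was the tight junction gene Cldn16 (0.37), whose rise was lost without any 1 array other than Lewis array 3. Scaling to a common median gave 11 lower members, and the deposited values gave 0.

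Cytochrome P450 and eicosanoid genes fell in Dahl S. Of 24 measured, 0 rose, 9 fell and 15 did not pass (11 lower adjusted over the list alone), with a median of -0.27 (adjusted p = 1.1e-06; adjusted p = 0.034 with an estimated correlation). Beside Cyp2c11, the omega-hydroxylase gene Cyp4f1 fell by 0.69 on the log2 scale (SE 0.06), Cyp2e1 by 0.72 (SE 0.07) and the epoxide hydrolase gene Ephx1 by 0.45 (SE 0.07). Glutathione S-transferase and conjugation genes split, with 3 of 27 higher, 11 lower and 13 not past the threshold (5 higher and 14 lower adjusted over the list alone), and a median of -0.17 (adjusted p = 6.9e-04; adjusted p = 0.120 with an estimated correlation). The theta-class genes Gstt1 and Gstt3 fell by 0.91 (SE 0.09) and 0.71 (SE 0.06), and the mu-class gene Gstm7 rose by 0.83 (SE 0.12), as did Gstm1 (0.90) and Gstm5 (0.47), which were named after their values were seen. Deposited values gave 1 lower P450 gene and 0 lower conjugation genes.

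The fatty acid oxidation list was lower in Dahl S, although Acsm3 and the thiolase gene Acaa2 (0.53, SE 0.06) rose. Of 30 measured, 2 rose, 11 fell and 17 did not pass (2 higher and 13 lower adjusted over the list alone), with a median of -0.16 (adjusted p = 2.0e-04; adjusted p = 0.034 with an estimated correlation). The peroxisome proliferation gene Pex11a fell by 0.86 (SE 0.09) on the log2 scale and the carnitine palmitoyltransferase gene Cpt1b by 0.78 (SE 0.09). The number that fell was 7 without Dahl S array 2 or 3 and 0 in the deposited values, where 1 rose and the list test gave adjusted p = 0.084. Oxidative phosphorylation and TCA cycle genes were not called as a list (median -0.06, adjusted p = 0.065; adjusted p = 0.233 with an estimated correlation): 2 of 32 were lower, Ndufa4 (-0.17, SE 0.05) and Ogdh (-0.22, SE 0.06), and 0 adjusted over the list alone. With scaling to a common median 11 were lower and the list passed (adjusted p = 3.6e-06), and it passed too without Lewis array 1 (0.0098), on ranks (0.034) and in the deposited values (0.036). The count was 0 without Dahl S array 2 or 3 and in the deposited values, and 1 without Lewis array 3 or Dahl S array 1. Antioxidant and NADPH oxidase genes gave 2 of 28 higher and 4 lower (2 and 5 adjusted over the list alone; list adjusted p = 0.163, and 0.0017 with scaling to a common median), with catalase, Cat (-0.34, SE 0.05), Msra (-0.41), Nox4 (-0.35) and Prdx6 (-0.28) lower, and Rac2 (0.68; 0.54 and adjusted p = 0.082 without Dahl S array 2) and Sod3 (0.36) higher. Prdx6 and Sod3 were named after their values were seen. The number lower was 9 with scaling to a common median, 2 without Dahl S array 1 and 0 in the deposited values. The number higher was 0 without Dahl S array 2 and 1 without Lewis array 2 or 3 or Dahl S array 1 or 3.

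Of 17 podocyte genes 2 rose, 5 fell and 10 did not pass (2 higher and 6 lower adjusted over the list alone), with a median of -0.14 (adjusted p = 0.044; adjusted p = 0.124 with an estimated correlation). Podxl, which encodes the surface protein podocalyxin, fell by 0.79 on the log2 scale (SE 0.08), and the transcription factor gene Tcf21 rose by 0.45 (SE 0.10), while the slit diaphragm gene Nphs1 differed by -0.10 (SE 0.12, adjusted p = 0.64). Ptpro (-0.41) fell as well, Enpep is counted as lower on its brighter probe set although its probe sets disagree, and of members named after their values were seen Wt1 (-0.36) and Plat fell and Nes (0.37) rose. The number that fell was 2 without Lewis array 2 or Dahl S array 2, 3 without Dahl S array 1 or 3, and 0 in the deposited values. The number that rose was 1 without Lewis array 3 or any 1 Dahl S array and 0 in the deposited values. The list call was lost without Lewis array 1 (adjusted p = 0.11) and without Dahl S array 1 (adjusted p = 0.055), in the deposited values (0.093), with the stricter filter (0.063), without a variance trend (0.051), as the mean of a gene's probe sets (0.097), on ranks (0.052) and over members of no other list (0.17). Of 21 endothelial genes 2 rose, 3 fell and 16 did not pass (2 higher and 8 lower adjusted over the list alone), with a median of -0.25 (adjusted p = 0.010; adjusted p = 0.120 with an estimated correlation), a call lost with the stricter filter (0.10) and in the deposited values (0.081). The fenestral diaphragm gene Plvap fell by 0.54 (SE 0.10) and Emcn, endomucin, by 0.36 (SE 0.08). Pecam1 fell by 0.40 (SE 0.11), a call lost without Lewis array 1 or any 1 Dahl S array (differences -0.43 to -0.30). Erg rose by 0.57 (SE 0.15), with 0.10 on its other probe set, and so did Vwf (0.46), which was named after its value was seen; at most 1 member rose without any 1 array, and 6 fell without Lewis array 3. The deposited values gave 1 higher and 0 lower. Smooth muscle, pericyte and fibroblast genes were not called as a list (5 of 15 higher, 1 lower; 5 and 2 adjusted over the list alone; adjusted p = 0.163, and 0.015 with the stricter filter), with Tagln up by 0.84 (SE 0.16) and the pericyte gene Cspg4 lower (-1.13, SE 0.18; -1.53 with no pseudocount and -0.66 with one of 64). The other members that rose were Des (0.63) and Pdgfra (0.45), and Cald1 (0.38) and Mylk (0.29), named after their values were seen. In this list 3 were higher without Lewis array 2 or any 1 of the 3 Dahl S arrays, and 2 were lower without Lewis array 3. The deposited values gave 2 higher and 0 lower.

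Of 11 adipocyte genes 1 rose and 3 fell (2 higher and 3 lower adjusted over the list alone; list adjusted p = 0.049, and adjusted p = 0.128 with an estimated correlation). The lipase gene Lpl fell by 1.66 on the log2 scale (SE 0.08) and the glucose transporter gene Slc2a4 by 1.30 (SE 0.12), while Fabp4, a fatty acid binding protein gene of fat and endothelial cells, rose by 0.71 (SE 0.10). Cidec fell by 0.33 (SE 0.10), a call lost without any 1 array other than Lewis array 1 (differences -0.35 to -0.28). This list call was lost without any 1 of Lewis arrays 1 and 3 and Dahl S arrays 1 and 2, where the adjusted p lay between 0.055 and 0.078, and under 6 further alternatives (0.055 to 0.13). Without Lewis array 1, 2 members rose. Of 2 measured adrenal genes Fdx1 gave -0.25 (SE 0.07, adjusted p = 0.028), a call lost without Lewis array 3 or any 1 Dahl S array (adjusted p 0.069 to 0.12) and in the deposited values, while of 3 skeletal muscle genes Casq1 rose by 0.71 (SE 0.09). Among 13 reference genes 1 was higher, Tubb5 (0.71, SE 0.10, with 0.10 on its other probe set), and 3 were without Lewis array 1. The reference list did not pass camera in the main setting (median 0.08, adjusted p = 0.062, and adjusted p = 0.133 with an estimated correlation). It did pass camera on ranks, and fry called it (fry adjusted p = 0.0061).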

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

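The tests of this part were chosen after the results they concern had been seen, except the counts over other splits of the arrays.

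Real and other splits of the arrays were compared. The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of 10 splits, the real one, as many probe sets were called in each direction (1343 higher and 1224 lower), and the highest count of the other splits was 0. Every other split mixes the strains, so the strain difference adds to the spread within its groups, and its count of 0 says little about chance. The real split called 18 gene lists, as many as in 1 of 10 splits. The other splits called 0 to 10 lists while 0 probe sets passed, so camera at its preset correlation can call lists where no probe set is called. These splits keep part of the strain difference and give no rate of false list calls.

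The poly-A spike controls, which no comparison uses, were 0.911 brighter in Dahl S on the log2 scale, beside 0.407 for the probe sets tested in the deposited values. Scanner gain or hybridization is argued against by the hybridization controls, whose difference was -0.0419 (SE 0.16 over the arrays, of which there are 3 per strain). An unequal yield of the labelling cannot be told apart from other causes: in 1 of 2 strains the spikes ordered the arrays as the probe sets did, and Lewis array 2 exceeded Lewis array 1 by 0.84 in the probe sets and by 0.11 in the spikes. Whether and when spikes were added is not given in the sources used here. A difference in the RNA content of the kidneys between strains stays open and was not tested.

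Differences of at least 2-fold could reflect a strain variant under the probes of 1 probe set, since the sequence of a strain can differ from that of the probes. Among 114 such genes outside the RT1 family, 21 had further tested probe sets. Of these 23 probe sets 22 showed the same direction (95.7%, exact 95% interval 78.1 to 99.9, taking probe sets as independent). This argues against such a variant as the general cause of the direction in these 21 genes. Of the 22, 20 passed the threshold, and 1 probe set passed in the opposite direction. Direction alone was scored, not size: Eri2 counted as agreeing, with 2.82 and 0.74 on its probe sets. Genes with a single probe set were not covered by this test. For RT1-CE5, 3 of 3 other probe sets shared the direction, while the other 3 RT1 genes of at least 2-fold had no further probe set, and whole haplotypes can differ between strains, so a variant cannot be told apart from a difference in RNA level there. A strain difference in expression, inherited or in response to salt, stays open as a hypothesis.

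Proximal tubule genes were lower in Dahl S, and a lower share of proximal tubule RNA with every gene lowered alike might account for that. Of the 31 members 9 (29.0%) differed from the list's median past the threshold, so the measured differences were not all alike. This share does not set the list apart. Over the tested lists it ran from 0% for oxidative phosphorylation to 76.2% for tubular injury genes. Among macrophage genes 1 of 20 (5%) differed from the list's median, which leaves a uniform shift open there. The scale understates the change of dim genes, so an equal loss can look unequal. The test therefore cannot tell whether a lower share of proximal tubule RNA contributed. The tested lists of other cell types moved apart, from a median of -0.25 for endothelial to 0.38 for macrophage genes. A difference in RNA integrity cannot be told apart from the strains here: for 0 of 3 control genes did all Dahl S arrays have 3'/5' ratios above all Lewis arrays, but the ratios differed by too little against their spread over 3 arrays to exclude it. A lower expression of part of the list, in response to salt or by strain, stays open and was not tested.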

How the results depend on the processing

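Alternatives chosen after seeing the data were probe sets with a single gene symbol alone (1043 higher, 992 lower) and list member counts without Lewis array 1. The filter on deposited values, the rule of the design, gave 1391 probe sets higher and 1180 lower with normalized values in the fit. The other alternatives were fixed beforehand. Counts moved by over 1.5 times in the deposited values (666 higher, 47 lower), with the stricter filter, which tested 7966 probe sets (842 and 796), with adjusted p under 0.01 (680 and 636), with a 2-fold minimum (134 and 110) and without 1 Dahl S array. Leaving out each array in turn gave 764 to 1451 probe sets higher and 727 to 1344 lower: 806 and 772 without Dahl S array 1, 834 and 804 without Dahl S array 2, and 764 and 727 without Dahl S array 3. A stricter threshold lowers a count by construction, and the stricter filter left 7966 of 15797 probe sets to call from. The cause of the other moves was not tested. Of the calls in the deposited values 646 were shared with the normalized values. Gene lists past the threshold numbered 18, and 8 with an estimated correlation; without each array in turn they were 16 to 19.

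The shared replicate numbers were checked as a pairing. Deviations of same-numbered arrays correlated at -0.05, -0.10 and 0.11, and 1 of 3 Dahl S arrays matched its own number best. No pairing by number was seen, though 3 arrays per strain are too few to exclude one. With a replicate block 1295 probe sets were higher and 1199 lower, and 17 lists passed; the adipocyte list lost its call (adjusted p = 0.055), and no other list or named gene changed its call.

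Of 109 named genes past the threshold 67 were tested and passed under every alternative other than the deposited values and the stricter thresholds, and 90 passed wherever they were tested: 29 were not tested with the stricter filter and 2 not with the filter on deposited values. Leaving out 1 array ended between 3 and 14 of these calls: 3, 5 and 3 for Lewis arrays 1, 2 and 3, and 8, 14 and 10 for Dahl S arrays 1, 2 and 3. In the deposited values, whose median lay 0.41 higher in Dahl S, differences reversed sign for Cidec (0.10), Fdx1 (0.15), Emcn (0.045), Pecam1 (0.022), Fxyd4 (0.0019), Nox4 (0.084), Ndufa4 (0.064), Ogdh (0.068), Ptpro (0.021), Nherf1 (0.057), Agt (0.34), Nr3c2 (0.32), Hsd11b2 (0.15), Slc12a3 (0.025) and Nphs1 (0.32); a common shift of the arrays accounts for that direction by construction. Enpep reversed as the mean of its probe sets (0.070), which disagree. Slc12a1 reversed with scaling to a common median (-0.13) and without Lewis array 3 (-0.015); the cause was not tested. The reference (housekeeping) list turned downward with scaling to a common median (adjusted p = 0.675), and the cause was not tested. Its adjusted p over the alternatives ran from 0.043, on ranks and past the threshold, to 0.708. The stricter filter ended the calls of 7 lists (chemokines, immediate-early, proliferation, erythrocyte, endothelial, podocyte and adipocyte genes), and 2 lists passed that had not. No other list changed direction under any alternative. The table gives no signal over background, so how far dim signals limit the calls is known only through the filters, under which 1085 were higher and 948 lower with no filter.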

Other observations

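Families formed from the stem of the gene symbols, a grouping chosen after the data were seen, were tested beside the fixed lists. They hold genes outside those lists but also members of them, such as Col3a1 and Cyp2c11, so their tests are not separate evidence. Of 166 families with at least 8 tested genes 11 passed camera's threshold, and 0 with an estimated correlation. The 11 include the single-letter stem P, with P2rx4 and P3h3, which is not a gene family. Annexins, calcium-dependent membrane-binding proteins, were higher in Dahl S in 5 of 8 genes and lower in 0, with Anxa5 at 0.65 and Anxa1 at 0.71 (family adjusted p = 0.0045; adjusted p = 0.667 with an estimated correlation). Proteins of the large ribosomal subunit (Rpl) were higher in 7 of 27 and lower in 0, by small amounts apart from Rpl6 (0.50; family adjusted p = 0.0027; adjusted p = 0.573 with an estimated correlation). The 7 include Rpl3 (0.23), another probe set of which passed in the opposite direction (-0.50, adjusted p = 0.036). Aldo-keto reductases fell in 6 of 10, among them the aldose reductase gene Akr1b1 (-0.62; family adjusted p = 0.0053; adjusted p = 0.948 with an estimated correlation).

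Solute carriers, the transporter family named Slc, were lower in 47 of 212 genes and higher in 16 (family adjusted p = 7.7e-04; adjusted p = 0.508 with an estimated correlation). The fructose transporter gene Slc2a5 (-0.89), the zinc transporter gene Slc30a2 (-0.98) and the mitochondrial carrier gene Slc25a25 (-1.08) fell, while the amino acid transporter gene Slc7a12 (1.25) and the phosphate transporter gene Slc34a2 (0.90) rose. Collagens rose in 11 of 20 genes and fell in 1, Col6a6 (-0.47), and those that rose included Col6a3 (0.69) and Col15a1 (0.66) from outside the fixed list (family adjusted p = 2.1e-04; adjusted p = 0.508 with an estimated correlation). Acyl-CoA thioesterases fell in 2 of 8, Acot3 (-0.93) and Acot4 (-0.94) (family adjusted p = 0.049; adjusted p = 0.816 with an estimated correlation). Of the interleukin and interleukin receptor genes (Il) 6 of 16 rose, with Il7 at 0.77 and Il6st at 0.60 (family adjusted p = 0.020; adjusted p = 0.739 with an estimated correlation). Of the cytochrome P450 genes (Cyp) 8 of 23 fell and 3 rose (family adjusted p = 0.049, and adjusted p = 0.816 with an estimated correlation). Among them Cyp1a1, outside the fixed P450 list, was higher in Dahl S (1.70) while Cyp2c11 was lower.

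A hypothesis written before its test was that genes with strain differences cluster along the genome, as would be so if linked sequence differences set the level of several neighbours. Over 9511 genes in the order of the GRCr8 assembly, leaving out overlapping genes and pairs of 1 name stem, 152 of 8704 adjacent pairs were called in the same direction. Permuted orders gave 121 on average (permutation p = 0.002, 10000 permutations), although the highest permuted order gave 161, so the observed count also lay within their range. This is consistent with a modest clustering of calls; adjacent genes of shared function or shared regulation would give it too, which was not tested. For pairs with at least 2-fold differences in both genes 1 was found (Prss35 and Snap91, which moved in opposite directions), where permuted orders gave 1.33 on average (permutation p = 0.7). With so few pairs by chance, a judgement made after that result was seen, this second test had little power to find clustering.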
